A study of Mus musculus with 82 samples.

How the data were processed

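The data are 82 libraries from the suprachiasmatic nucleus (SCN), the hypothalamic nucleus that holds the central circadian pacemaker, of C57BL/6 mice aged 8 weeks. Per the labels' protocols, tissue sections were stained with cresyl violet and a grid of hexagons with a largest radius of 40 µm was cut out by laser capture microdissection. The hexagons were chosen by the grid and not by a marker. Libraries were made with Smart-seq2, a full-length cDNA method for very small inputs, and Tn5 tagmentation. The labels give each hexagon a medial-lateral, a dorsal-ventral and an anterior-posterior coordinate, with no unit and without saying which end of an axis is which. They name no animal, sex or collection time. Hexagons may therefore share an animal, so p-values over hexagons are too small and measure only the spread between hexagons.

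The deposited count table holds whole-number counts for 27515 genes, made by the authors. The submitters' processing notes name bcl2fastq 2, STAR and the build GRCm38, with no role or order. The counting program, its strand setting and the annotation are not given in the sources used here. The deposited RPKM table holds 27055 of these genes. Its values equal the deposited counts divided by the gene length in the file and by the library total over the genes in that table, to within a relative deviation of 5.2e-15, so RPKM was not treated as independent evidence. The genes absent from it carry 0.0316% of all counts. Symbols came from the RPKM table for 27055 gene IDs and from a reference table for 451 more, and 9 stayed without one. Gene positions are those of GENCODE M21 on GRCm38, matched on the gene ID without its version. Among 81 genes named by rule, 24 have an exon that overlaps another annotated gene, 17 of them on the other strand, such as Nr1d1 with Thra and Rtl1 with several microRNAs. Reads there cannot be assigned with certainty without a known strand setting. The same holds for the globin, ribosomal protein and mitochondrial genes, which have near-identical copies or pseudogenes.

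Total counts ran from 11905 to 2843366 per library (median 542267.5) and genes detected from 2549 to 13419 (median 11550). No library pair was identical, and the highest correlation of log2 CPM between libraries was 0.846. The 5 libraries with a total below the median divided by 3 were kept, and were left out as an alternative. Hexagons were assigned to 9 sections by the anterior-posterior coordinate, numbered from the lowest value. The description label of each hexagon opens with a letter, A to H, which was read here as a library set. That reading is an inference, and the letter follows the sections. Sets A, D, E, F and H each span 2 neighbouring sections, and sections 4 to 7 are each divided between 2 sets.

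Genes with 10 or more counts in 10 or more libraries were tested, which left 11469. Slopes along the dorsal-ventral and medial-lateral coordinates came from edgeR's quasi-likelihood test (version 4.0.16 in R 4.3.3, TMM scaling, robust) on 82 hexagons, with section as a factor and both coordinates in the model. The same tool tested 5 terms together, namely both coordinates, their squares and their product. The lone hexagon of section 9 carries no weight in these slopes. The anterior-posterior slope was fitted to counts summed per section over the 8 sections with 4 or more hexagons, which left out section 9. That fit had no term for the dorsal-ventral or medial-lateral coordinate. A slope is the log2 change per 100 coordinate units, and its standard error was taken as the slope's size over the square root of its F statistic. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Biological coefficients of variation were 0.73 for hexagons and 0.306 for section sums. CPM values use TMM-adjusted library sizes, and log2(CPM + 1) was used for correlations.

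The gene lists, the rule for named genes, 8 gene pairs and the slope, 5-term, list and pair tests were fixed before the data were examined. Added afterwards were 4 alternatives, 2 gene pairs and tests of library sets, gene length, neuron shares, a Vip-rich hexagon, respiratory chain and ATP synthase genes, changes of slope between sections and section peaks. The lists covered SCN neuropeptides, circadian clock genes, SCN-enriched regulators and receptors, immediate early genes, GABA signalling, membrane excitability channels, mitochondrially encoded transcripts and cytosolic ribosomal proteins. Further lists held markers of glutamatergic neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial cells, mural cells, ependymal cells and tanycytes, meningeal fibroblasts and erythrocytes. For each axis the rule took genes with adjusted p under 0.05, a mean CPM of 20 or more and a slope of one sign in at least 6 of 8 sections, or for the anterior-posterior axis the same sign with each section left out. It named the 10 largest slopes in each direction, up to 4 called members per list, and always Avp, Vip, Grp, Nms, Prok2 and Cck. Lists with 3 or more tested genes were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 16 lists so tested, and also with an estimated correlation. As another alternative, fry tested whether a list's genes move on balance one way, without a comparison with other genes. Pair correlations used residuals from section means, with 1e+05 two-sided permutations within sections.

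The slope, 5-term, camera and pair tests were also run on simulated data. Counts were drawn for each gene on its own with the real means and library sizes, and 200 genes were given known slopes. No section or library set effects and no correlation between genes were simulated, so the false calls and camera values below do not cover those. At a slope of 0.5, 79% were recovered on the dorsal-ventral coordinate, 51% on the medial-lateral coordinate and 55% on the anterior-posterior coordinate, and at a slope of 1 the shares were 99%, 96% and 96%. False calls were 1, 2 and 8 of the unchanged genes among 11469. For the 5-term test, 70% and 98% were recovered with 3 false calls. In a camera test on the dorsal-ventral simulation, a list of genes with a slope of 0.5 gave p = 5.11e-47 and one of unchanged genes p = 0.903. For the pair correlations, 98.5% of 200 simulated pairs with a slope of 0.5 on unit noise and 6.0% of 200 unrelated pairs had p under 0.05.

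Alternatives were DESeq2 1.42.0, 2 other scalings, 2 other filters, limma on log2(RPKM + 1) and log2(RPKM + 0.1), removal of the low-depth libraries, library set or genes detected as covariates, a split at the median coordinate of each section, hexagon-level fits of the anterior-posterior slope, and leaving out each section. Results of some single members of the lists are not reported here.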

Results

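Transcripts were counted in 82 hexagons of the mouse SCN at 9 anterior-posterior coordinates from 47 to 431, in steps of 48. Sections 1 to 9, numbered from the lowest coordinate, held 4, 6, 12, 14, 12, 14, 13, 6 and 1 hexagons. Dorsal-ventral coordinates ran from 301 to 917 and medial-lateral coordinates from 1100 to 1517. The labels give positions and no treatment, so the comparisons ask which transcripts differ with the position of a hexagon. Whether every hexagon lay within the SCN was not tested. Some held little peptide transcript: replicate 12 of section 7, at a medial-lateral coordinate of 1414, had 3.05 CPM of Nms and 3086 CPM of the oligodendrocyte marker Mbp. Means over hexagons were 165 and 1110 CPM. Others of high coordinate held more Nms, such as replicate 12 of section 6, at 1395, with 421 CPM. Total counts per library ranged from 11905 to 2843366, and summed counts per section from 895060 to 17639264. The shallowest library, replicate 4 of section 4, had 2549 genes detected and 8.02% mitochondrial counts, against medians of 11550 genes and 1.48%. The first principal component, with 11.2% of the variance, had r = -0.927 with genes detected over the 82 libraries, and its r with each coordinate lay between -0.152 and -0.0109. Slopes below are log2 changes per 100 coordinate units with their standard error (SE), and CPM means of coordinate groups are not adjusted for section.

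Vip, the neuropeptide of ventral core neurons that couples SCN cells, rose with the dorsal-ventral coordinate, with a slope of 1.54 (SE 0.17, edgeR adjusted p = 1.39e-09). Its level was 213 ± 395 CPM (SD, n = 27) in the hexagons of lowest coordinate (301 to 578), 869 ± 1592 CPM (n = 28) in the middle ones, and 4287 ± 5236 CPM (n = 27) in those of highest coordinate (743 to 917). The slope was positive in 7 of 8 sections, but its sign in sections 1 to 3 carries little. In section 1 all Vip lay in 1 hexagon, in section 2 no hexagon reached 3 Vip counts, and in section 3 only 3 of 12 did. Ppp1r1a, an inhibitor of protein phosphatase, rose from 74.8 ± 73.0 to 172 ± 140 CPM (slope 0.47, SE 0.06, adjusted p = 3.74e-07). Penk, the enkephalin precursor, fell from 274 ± 239 to 77.2 ± 59.2 CPM (slope -0.43, SE 0.10, adjusted p = 0.0101), and Syt1, the calcium sensor of synaptic vesicle release, from 533 ± 260 to 296 ± 240 CPM (slope -0.36, SE 0.06, adjusted p = 4.88e-05). Avp, the neuropeptide of the dorsomedial shell, did not pass, with 434 ± 268 CPM at low and 256 ± 257 CPM at high coordinates (slope -0.27, SE 0.11, adjusted p = 0.402). The labels do not say which end of this axis is ventral, and Vip was higher at higher coordinates.

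**Figure D1:**
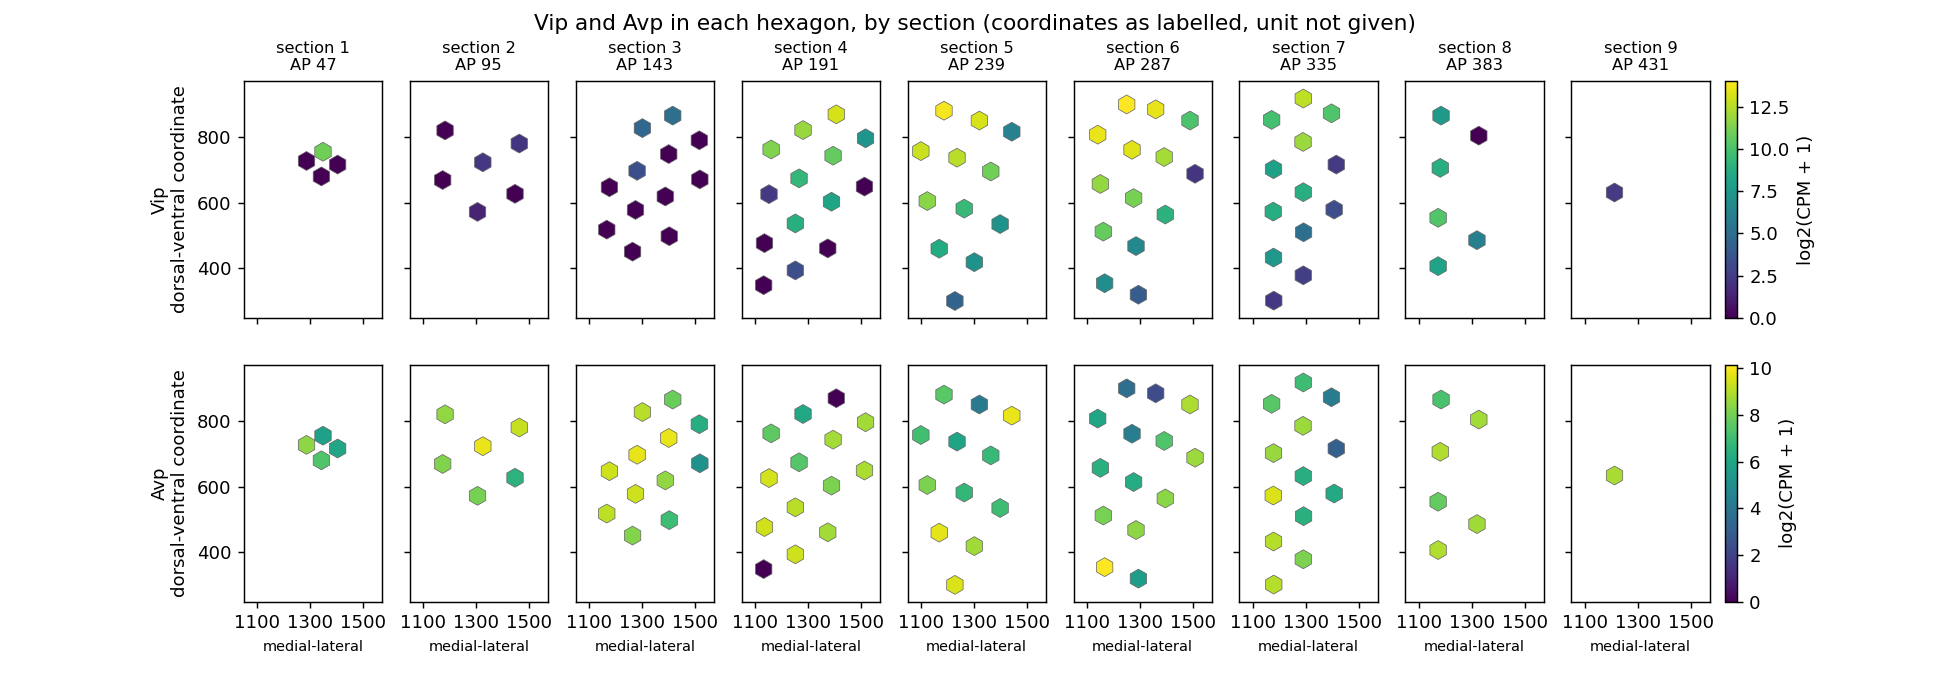
Each panel shows the hexagons of 1 section at their medial-lateral (x) and dorsal-ventral (y) coordinates, in label units, coloured by log2(CPM + 1) of Vip (top) or Avp (bottom), 1 point per hexagon and no error bars. Vip was highest in hexagons of high dorsal-ventral coordinate in sections 4 to 7, up to 16900 CPM in section 6, and Avp reached 1126 CPM in a section 6 hexagon of low coordinate.

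In all, 91 of 11469 genes passed along the dorsal-ventral coordinate, 58 higher and 33 lower at higher coordinates. Other genes named by the rule that rose were Npy6r, a neuropeptide Y receptor (slope 0.82), Nov (0.68), the sialyltransferase St3gal1 (0.54), the Wnt modulator Sfrp2 (0.51), Lzts1 (0.49), the transcription factor Pou2f2 (0.44) and Cadps2, which acts in dense-core vesicle release (0.43). Those that fell were the orphan receptor Gpr101 (-0.67), the neuronal nitric oxide synthase Nos1 (-0.47), the sodium-calcium exchanger Slc8a3 (-0.45), the GABA receptor subunit Gabrq (-0.40), Mef2c (-0.34), Pcdh11x (-0.33) and Khdrbs2 (-0.27). The adjusted p-values of these genes ran from 1.52e-04 to 0.0399. Hbb-bt, a beta globin, rose with a slope of 1.23 (SE 0.29, adjusted p = 0.0131), and was detected in 37.8% of libraries. The peptides Grp (slope 0.28, SE 0.21), Nms (0.06, SE 0.08), Prok2 (0.16, SE 0.12) and Cck (0.14, SE 0.12) did not pass, with adjusted p-values from 0.838 to 0.976.

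Among fixed lists along this axis, the SCN-enriched regulators and receptors lay higher than other genes (camera adjusted p = 4.48e-04). None of 12 tested members passed over all genes, and 3 rose (Lhx1, Syt10 and Six3) when adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.179). GABA signalling lay lower (camera adjusted p = 0.00712, and adjusted p = 0.161 with an estimated correlation). Among its 11 members, Gad2, an enzyme of GABA synthesis, fell when adjusted over the list alone. Without the 5 low-depth libraries its adjusted p was 0.0632. Mitochondrially encoded transcripts lay lower, with 11 of 12 slopes negative (camera adjusted p = 8.72e-10, and adjusted p = 0.073 with an estimated correlation). Of these, mt-Nd5 (slope -0.09, SE 0.02), mt-Nd2 (-0.15, SE 0.03) and mt-Nd1 (-0.07, SE 0.02) fell, and 8 fell when adjusted over the list alone. Cytosolic ribosomal proteins lay lower, with 66 of 73 slopes negative (camera adjusted p = 5.23e-16, and adjusted p = 0.0403 with an estimated correlation). Rpl3, Rpl24, Rpl37 and Rpl35a fell, with slopes between -0.09 and -0.08, and 19 genes fell when adjusted over the list alone. In the neuropeptide list Vip rose and Penk fell among 13 tested. Adjusted over the list alone, Pdyn, Avp, Cartpt and Sst fell too (camera adjusted p = 0.543). Among the 5 erythrocyte genes, 4 globins rose when adjusted over the list alone (camera adjusted p = 0.0979). The clock list had no called member (camera adjusted p = 0.736), and the 11 lists not past the threshold besides the neuropeptides had adjusted p-values from 0.0979 to 0.736. The lists of glutamatergic neurons and of ependymal cells and tanycytes had 1 tested gene each and were not tested on any axis. Over hexagons that may share an animal these p-values are too small. The count of 91 genes was 56, 47, 49 and 138 without section 4, 5, 6 or 8, and scaling by library size alone gave 58 higher and 51 lower.

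Along the medial-lateral coordinate, transcripts of the circadian clock fell. Per1, a light- and clock-driven repressor of the clock, went from 191.8 ± 75.02 CPM (SD, n = 27) at coordinates of 1100 to 1228 to 106 ± 39.2 CPM (n = 27) at 1348 to 1517 (slope -0.34, SE 0.06, edgeR adjusted p = 8.64e-04), with a negative slope in 8 of 8 sections. The clock output factor Hlf fell from 251 ± 103 to 134 ± 59.9 CPM (slope -0.33, SE 0.07, adjusted p = 0.00367), and the nuclear receptor Rorb from 1687 ± 555 to 995 ± 387 CPM (slope -0.25, SE 0.06, adjusted p = 0.0119). Nr1d1, a repressor of Arntl, had a slope of -0.23 (SE 0.06, adjusted p = 0.0247) and Per3 one of -0.25 (SE 0.07, adjusted p = 0.0492). Of 23 clock genes, 20 had negative slopes, 5 fell, and 9 fell when adjusted over the list alone, Per2, Clock and Rora among them. The list lay lower than other genes (camera adjusted p = 4.15e-09, and adjusted p = 0.00744 with an estimated correlation). Arntl, with a slope of -0.02 (SE 0.09), and Cry2, with 0.03 (SE 0.07), did not pass.

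**Figure D2:**
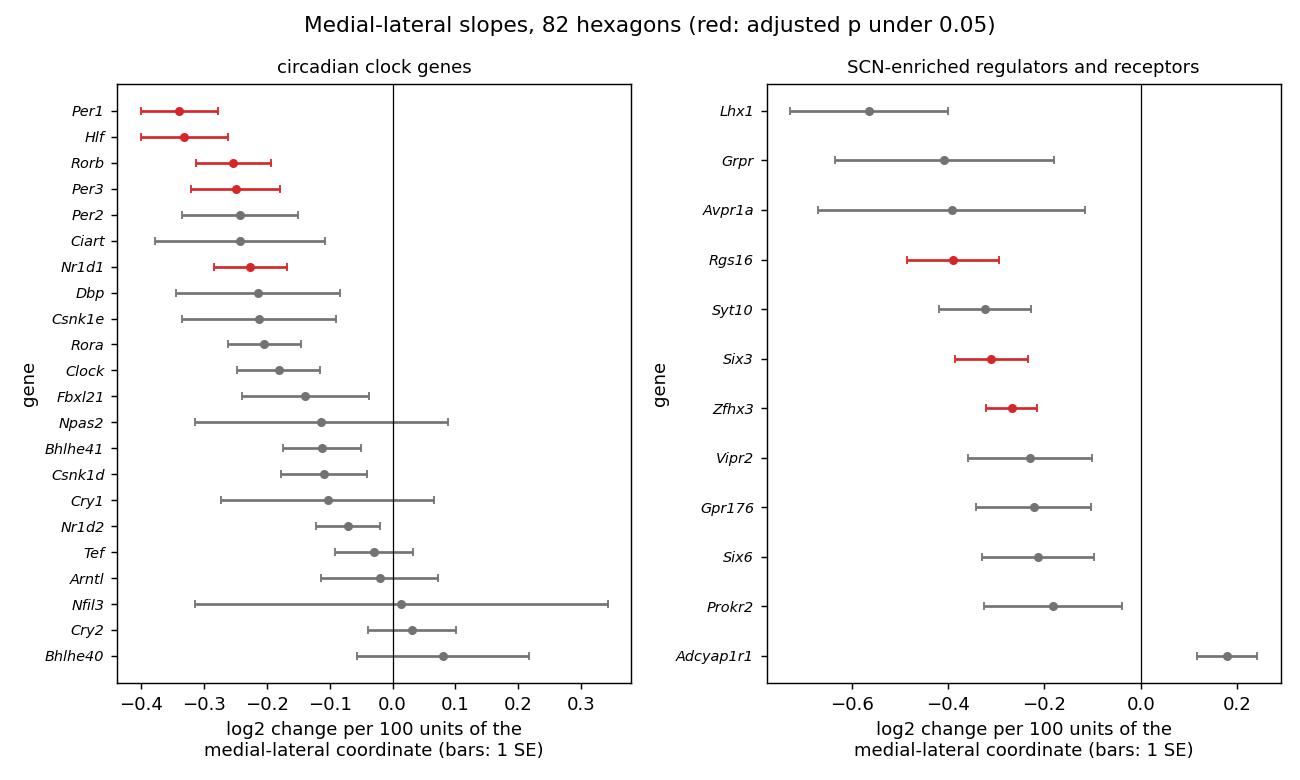
Points are medial-lateral slopes (x, log2 change per 100 units) of reported genes (y) of the clock list (left) and of the SCN-enriched list (right) over 82 hexagons, bars are 1 SE, and red marks adjusted p under 0.05. Per1 lies at -0.34 and Zfhx3 at -0.27, and 11 of 12 SCN-enriched genes lie below 0, with Adcyap1r1 at 0.18.

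In all, 158 genes passed along the medial-lateral coordinate, 94 higher and 64 lower at higher coordinates. Calcr, the calcitonin receptor, fell from 261 ± 238 to 38.2 ± 54.6 CPM (slope -0.97, SE 0.21, adjusted p = 0.00469), and Peg10, an imprinted gene derived from a retrotransposon, from 522 ± 241 to 202 ± 105 CPM (slope -0.45, SE 0.08, adjusted p = 8.64e-04). Also lower were St3gal1 (-0.86), Mcub, a subunit that dampens mitochondrial calcium uptake (-0.67), Hs3st1 (-0.64), the small GTPase Rasl11b (-0.63), Mpped2 (-0.61), Chmp1b (-0.53), Cdc14a (-0.48) and Ppp1r1a (-0.47). Cplx1, a regulator of vesicle fusion, rose from 84.2 ± 73.0 to 260 ± 270 CPM (slope 0.55, SE 0.13, adjusted p = 0.0119). Further genes that rose were Cntnap1, a protein of the axon beside the node of Ranvier (0.78), Lgi3 (0.70), the vesicle protein Vamp1 (0.68), the neuronal surface protein Thy1 (0.58), Dscam (0.56), Rgs10 (0.55), Mtfp1 (0.50), Slc8a3 (0.49) and Gfra4 (0.47). Vip did not pass, with a slope of -0.99 (SE 0.28, adjusted p = 0.0569), nor did Prok2 (-0.54, SE 0.20), Nms (-0.29, SE 0.12), Avp (-0.03, SE 0.16), Grp (-0.08, SE 0.29) or Cck (0.23, SE 0.18), with adjusted p-values from 0.176 to 0.974. Adjusted over the neuropeptide list alone, Vip, Prok2 and Sst fell and Trh rose.

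The SCN-enriched regulators and receptors lay lower along the medial-lateral coordinate (camera adjusted p = 4.76e-08, and adjusted p = 0.0184 with an estimated correlation). Zfhx3 and Six3, transcription factors of the SCN, and Rgs16, a regulator of G-protein signalling, fell, with slopes of -0.27 (SE 0.05), -0.31 (SE 0.08) and -0.39 (SE 0.10). Adjusted over the list alone, 5 of 12 fell and Adcyap1r1, the PACAP receptor, rose. Mitochondrially encoded transcripts lay higher, with 12 of 12 slopes positive (camera adjusted p = 1.33e-12, and adjusted p = 0.0184 with an estimated correlation). Of these mt-Co1, mt-Nd5 and mt-Cytb rose, with slopes from 0.13 to 0.14, and 8 rose when adjusted over the list alone. Cytosolic ribosomal proteins lay higher, with 65 of 73 slopes positive (camera adjusted p = 1.20e-15, and adjusted p = 0.0184 with an estimated correlation). Among them 5 rose, including Rpl11 with a slope of 0.16 and Rpl24, Rpl35a and Rps14 with 0.12 to 0.13, and 14 rose when adjusted over the list alone. Astrocyte markers lay higher, with 12 of 12 slopes positive (camera adjusted p = 1.69e-06, and adjusted p = 0.0918 with an estimated correlation). S100b rose from 94.9 ± 44.1 to 159 ± 90.4 CPM (slope 0.27, SE 0.07), and Agt and Slc1a3 rose too when adjusted over the list alone. GABA signalling lay higher (camera adjusted p = 0.00846, and adjusted p = 0.109 with an estimated correlation), with no called member over all genes. Oligodendrocyte markers lay higher, with 11 of 11 slopes positive and no called member on either adjustment (camera adjusted p = 0.00146, and adjusted p = 0.443 with an estimated correlation). Of 4 meningeal fibroblast genes, Slc6a13, a GABA transporter of the meninges, fell from 40.8 ± 94.4 to 1.11 ± 2.83 CPM and Dcn, a collagen-binding proteoglycan, from 28.9 ± 54.3 to 1.53 ± 5.44 CPM (camera adjusted p of the list = 0.369). Other lists, the neuropeptides, immediate early genes and channels among them, had adjusted p-values from 0.358 to 0.993.

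Within sections, 36.0% of the medial-lateral spread of hexagons followed the library set, against 2.33% of the dorsal-ventral spread. With library set as a further factor, 14 genes passed along the medial-lateral coordinate, and 31, 73 and 85 passed without section 7, 6 or 3. Without section 7, 9 were higher and 22 lower. In the fit with library set as a factor, the clock list kept its call with an estimated correlation (adjusted p = 0.0328). In the same fit the SCN-enriched, mitochondrial and ribosomal lists had adjusted p = 0.0967 with an estimated correlation, and the oligodendrocyte list had a camera adjusted p of 0.185. With the trend in gene length and mean expression removed, the median slope statistic went from 2.87 to 1.78 for the mitochondrial list and from 1.61 to 0.933 for the ribosomal list (cameraPR p = 4.21e-06 and 1.06e-06). Hexagons may share an animal, which makes the p-values of this axis too small.

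Between the 91 and 158 genes of the axes, 22 were shared, where independent lists would share 1.25. All 22 had opposite signs, among them Syt1, Ppp1r1a, Slc8a3, St3gal1 and mt-Nd5. Within sections the coordinates had r = 0.265 over hexagons, so that the slope estimates of one gene have a correlation of -0.265 under equal weights. The 5-term test, which also detects a peak or trough within sections, called 233 genes, of which 86 had passed on neither slope. Among the peptides Vip (edgeR adjusted p = 1.99e-09), Grp (0.00850) and Prok2 (0.0115) passed this test, and Nms (0.133), Avp (0.235) and Cck (0.827) did not. The count was 123, 85 and 147 without section 5, 6 or 7, and 140 with library set as a factor. These tests too treat hexagons that may share an animal as separate, and their p-values are too small.

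Along the anterior-posterior coordinate, counts summed over 8 sections gave 28 genes, 13 higher and 15 lower at higher coordinates. The dorsal-ventral and medial-lateral coordinates were not in this fit, so where the summed hexagons lay within each section can enter these slopes. Over hexagons, with both of these coordinates in the model, edgeR called 337 genes, with 22 of the 28 among them. St8sia6, a sialyltransferase, rose from 40.6 ± 10.8 CPM (SD, n = 3) in sections 1 to 3 to 147 ± 51.4 CPM (n = 3) in sections 6 to 8 (slope 0.77, SE 0.08, edgeR adjusted p = 5.56e-04). Penk rose from 87.7 ± 8.38 to 264 ± 74.8 CPM (slope 0.62, SE 0.10, adjusted p = 0.0231), and Rgs16 from 431 ± 56.7 to 908 ± 116 CPM (slope 0.40, SE 0.07, adjusted p = 0.0254). Meg3, a maternally expressed long noncoding RNA, fell from 3201 ± 597 to 1663 ± 92.3 CPM (slope -0.38, SE 0.06, adjusted p = 0.0208). Rtl1, paternally expressed from the same imprinted region of chromosome 12, fell from 98.5 ± 42.8 to 27.7 ± 3.87 CPM (slope -0.73, SE 0.10, adjusted p = 0.0181). Other genes that rose were Slitrk5 (0.75), the kinase Plk2 (0.55), the guanine deaminase Gda (0.54), Tmem55a (0.50), Sh3gl2 (0.41), Usp46 (0.40) and Hadhb (0.38). Those that fell were Cfap44 (-0.72), the GABA receptor subunit Gabre (-0.71), Zfp318 (-0.53), Plekhn1 (-0.51), the calcium channel subunit Cacna2d2 (-0.44), Exd2 (-0.41), 5330417C22Rik (-0.39) and the mitochondrial tRNA synthetase Lars2 (-0.39).

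None of the 6 peptides named in advance passed along this axis, the nearest being Nms with a slope of 0.51 (SE 0.11, edgeR adjusted p = 0.0555). Prok2, which carries SCN output, averaged 30.0 ± 33.8 CPM (SD, n = 4) over the hexagons of section 1 and 338 ± 235 CPM (n = 14) in section 6 (slope 1.24, SE 0.32, adjusted p = 0.137). Grp averaged 102 ± 126 CPM (n = 14) in section 6 and 20.7 ± 45.0 CPM (n = 6) in section 8 (slope 1.99, SE 0.81, adjusted p = 0.289). Vip averaged 499 ± 997 CPM (n = 4) in section 1, all from 1 hexagon of 1995 CPM that also enters the slope. It averaged 5.46 ± 11.1 CPM (n = 12) in section 3, 4661 ± 5694 CPM (n = 14) in section 6 and 361 ± 432 CPM (n = 6) in section 8 (slope 1.28, SE 1.21, adjusted p = 0.661). In section 2 no hexagon reached 3 Vip counts. Cck averaged 173 ± 144 CPM (n = 12) in section 3 and 25.3 ± 25.3 CPM (n = 13) in section 7 (slope -0.45, SE 0.34, adjusted p = 0.553). Avp had a slope of -0.04 (SE 0.09, adjusted p = 0.878).

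**Figure D3:**
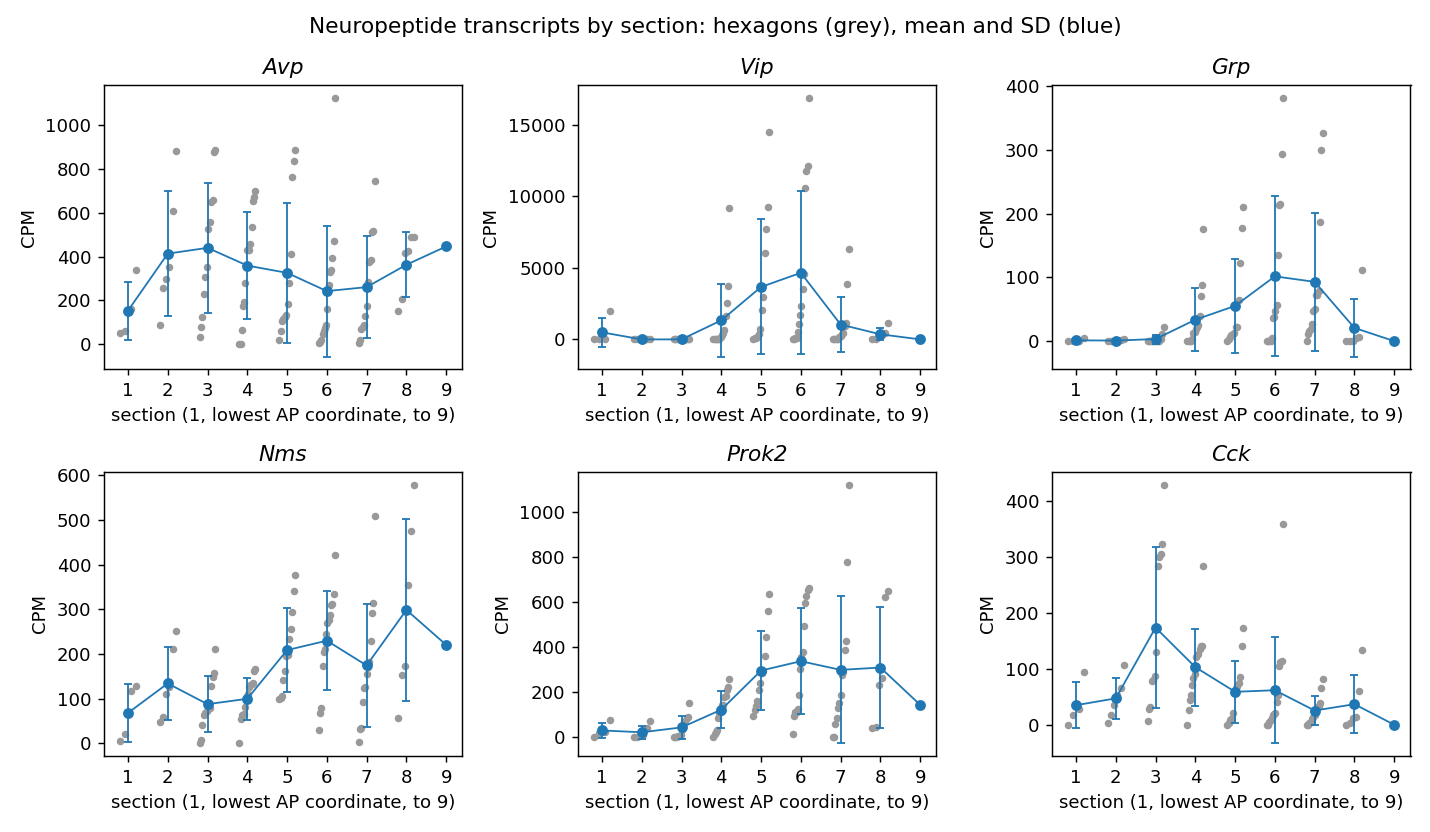
Grey points are CPM of 6 neuropeptide transcripts (y, linear, each panel with its own scale) in each hexagon by section (x, 1 to 9 by rising anterior-posterior coordinate), and blue points with bars are section means and SD, with no SD for the single hexagon of section 9. Mean Vip was 1.47 CPM in section 2 and 4661 CPM in section 6, and mean Prok2 21.8 CPM and 338 CPM.

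Among lists along the anterior-posterior coordinate, SCN-enriched regulators and receptors lay higher (camera adjusted p = 2.30e-04, and adjusted p = 0.238 with an estimated correlation). Rgs16 rose, and with it the vasopressin receptor Avpr1a and the Grp receptor Grpr when adjusted over the list alone. Channels of membrane excitability lay lower, with 11 of 15 slopes negative and no called member (camera adjusted p = 0.00932, and adjusted p = 0.238 with an estimated correlation). Oligodendrocyte markers (camera adjusted p = 0.00932), cytosolic ribosomal proteins (7.96e-04) and mitochondrially encoded transcripts (0.0318) lay higher, with no called member, and mt-Nd1 and mt-Cytb rose when adjusted over the list alone. With an estimated correlation each of these 3 lists had adjusted p = 0.708. Among the neuropeptides Penk rose, and Nms and Prok2 rose and Nts fell when adjusted over the list alone (camera adjusted p = 0.0921, with a median slope of -0.04 against a mean of 0.20). Astrocyte markers had a camera adjusted p of 0.0504, and of 0.0474 without the 5 low-depth libraries. The remaining lists had adjusted p-values from 0.244 to 0.984. Library sets follow the sections. With library set as a factor in a fit over hexagons, edgeR called 0 genes, with 408 at unadjusted p under 0.05. Without such a factor, limma on section means of RPKM called 2. The count was 14, 16, 12, 1 and 79 without section 1, 4, 6, 7 or 8, and scaling by library size alone gave 8 higher and 16 lower. Sections may come from the same animal, and p-values over them are then too small.

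For the pairs fixed in advance, correlations of log2(CPM + 1) were computed over 82 hexagons after section means were removed, with 2-sided permutation tests adjusted over 8 pairs. Avp and Nms rose and fell together (r = 0.501, p = 7e-05, adjusted p = 0.00048, and rho = 0.331, p = 0.00217). Without the 2 hexagons farthest from the median of the first gene of a pair, here Avp, r was 0.386, and within library sets it ran from -0.602 to 0.911, positive in 5 of 8. Avp with Prok2 gave r = 0.386 (p = 0.00105, adjusted p = 0.0028) and rho = 0.318 (p = 0.00278), with r = 0.359 without 2 hexagons and -0.0838 to 0.762 within sets. Grp with Vip gave r = 0.446 (p = 0.00012, adjusted p = 0.00048) and rho = 0.384 (p = 0.00099), with 0.432 without 2 hexagons and -0.312 to 0.877 within sets. Vip with Nms gave r = 0.348 (p = 0.00214, adjusted p = 0.00428) and rho = 0.299 (p = 0.00836), with 0.352 without 2 hexagons and -0.191 to 0.547 within sets. Avp was lower where Grp was higher (r = -0.351, p = 0.00385, adjusted p = 0.00513, and rho = -0.387, p = 0.00068), with -0.45 without 2 hexagons and -0.774 to 0.31 within sets. Avp with Vip did not pass by Pearson's r (-0.25, p = 0.0597, adjusted p = 0.0597) and passed by rho (-0.33, p = 0.00539, adjusted p = 0.00862), with r = -0.319 without 2 hexagons and -0.905 to 0.191 within sets.

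Cck with C1ql3, a synaptic organizer, gave r = 0.336 (p = 0.00362, adjusted p = 0.00513) and rho = 0.213 (p = 0.0642), and Cck with the growth factor Bdnf gave r = 0.281 (p = 0.0156, adjusted p = 0.0178) and rho = 0.209 (p = 0.0554), so that neither passed by rho. Without 2 hexagons these r were 0.327 and 0.339. Within sets, r ran from -0.251 to 0.849 for the C1ql3 pair and from -0.272 to 0.708 for the Bdnf pair. With the 5 position terms removed, Vip with Nms (r = 0.256, adjusted p = 0.0558) and Grp with Vip (r = 0.278, adjusted p = 0.0533) no longer passed. Without the 5 low-depth libraries, chosen after the data were seen, Avp with Vip passed by Pearson's r (-0.392, p = 0.00134), and Avp with Grp gave -0.493. Every pair with a positive r had a lower r there, such as 0.389 for Avp with Nms, 0.366 for Grp with Vip and 0.256 for Vip with Nms. All 8 pairs passed there by Pearson's r. The shallowest library, replicate 4 of section 4, held 0 CPM of each transcript of these pairs. Hexagons may share an animal, so these p-values are too small.

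On GRCm38, Vip (ENSMUSG00000019772.5) lies on chromosome 10 from 5639218 to 5647617 on the plus strand, Penk (ENSMUSG00000045573.9) on chromosome 4 from 4133531 to 4138819 on the minus strand, and Per1 (ENSMUSG00000020893.17) on chromosome 11 from 69095217 to 69109960 on the plus strand. Calcr (ENSMUSG00000023964.15) lies on chromosome 6 from 3685680 to 3764714 on the minus strand, Avp (ENSMUSG00000037727.6) on chromosome 2 from 130580620 to 130582554 on the minus strand, and St8sia6 (ENSMUSG00000003418.11) on chromosome 2 from 13651021 to 13794064 on the minus strand. Meg3 (ENSMUSG00000021268.17) spans 109541001 to 109571726 on the plus strand and Rtl1 (ENSMUSG00000085925.3) 109589193 to 109600330 on the minus strand of chromosome 12. All are annotated as protein coding except Meg3, a lincRNA. Of these, Penk, St8sia6, Meg3 and Rtl1 overlap exons of genes on the other strand, whose reads can be among their counts.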

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

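The tests of library sets, of neuron shares and of the Vip hexagon were chosen only after the result was seen. The test of gene length was added after the data were examined but before its own result was seen, and that of positions drawn anew was set before its result.

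Among 27 groups of 4 to 10 hexagons, 1 measure and section at a time, 5 had a hexagon far from the others. For normally spread values chance marks about 1 in 20 groups, a share that need not hold for CPM with many values near 0. Sections 3 to 7, with more than 10 hexagons each, and section 9 were not screened. In section 1, replicate 1 had a total count of 948827 and the next 435357. In section 8, replicate 6 had 2.48% mitochondrial counts and the next 1.86%. In section 1, Vip stood at 1995 CPM in replicate 2 and at 0 in the others, and Grp at 4.93 CPM in replicate 4 and at 0 in the others. With the others at 0 any value stands apart by construction, and no hexagon of section 1 held 3 Grp counts. In section 8, Grp stood at 112 CPM in replicate 4 and at 6.69 CPM in the next. The hexagon of section 9 carries no weight in the main slopes but enters the anterior-posterior fits over hexagons. It held signal above the limit that a count of 0 allows, with 447 CPM of Avp (395 counts), 221 CPM of Nms (195 counts), 144 CPM of Prok2 (127 counts) and 4.52 CPM of Vip (4 counts), and had 0 counts of Grp and of Cck.

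The counts of genes were larger with the real positions than with any positions drawn anew. Such draws separate neighbouring hexagons and neighbouring sections, which may be alike for other reasons. They therefore speak only against an arrangement without such likeness. Positions drawn anew among the hexagons of each section, 40 arrangements with the real one, gave at most 6 genes in another arrangement against 91 along the dorsal-ventral coordinate, 3 against 158 along the medial-lateral coordinate and 9 against 233 in the 5-term test. Anterior-posterior values drawn anew among the 8 sections, 100 orders with the real one, gave at most 15 genes in another order against 28. In each case 1 arrangement, the real one, gave as many. These draws leave library sets out of account. With set as a factor 72, 14 and 140 genes passed in the dorsal-ventral, medial-lateral and 5-term tests. For the anterior-posterior slope set was added only in a fit over hexagons, which called 0 genes with set and 337 without.

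The clock list fell with the medial-lateral coordinate, 1 part of a pattern of 158 genes. Gene length does not account for it, since the list stayed apart with the trend in length and mean expression removed (cameraPR p = 9.35e-13). A lower share of neurons is argued against but not excluded by a median slope of 0.0973 over 8 pan-neuronal genes, with 7 of 8 above 0. Of these only Syt1 passed (slope 0.40, edgeR adjusted p = 0.00457). Slopes of glial markers were positive too, in 12 of 12 astrocyte and 11 of 11 oligodendrocyte genes. Library sets as the whole source of the 158 slopes are argued against by a median ratio of 0.952 (quartiles 0.841 and 1.06) between slopes with and without set as a factor. All 158 kept their sign, 153 stayed at unadjusted p under 0.05 and standard errors grew by a median ratio of 1.25, and what ended the calls was not separated further. For the clock list the adjusted p was 3.51e-07 with set as a factor, but its median slope went from -0.18 to -0.14, a ratio of 0.75, so the part that follows sets cannot be told apart, and a candidate explanation of the rest is fewer SCN neurons among the neurons there, since the SCN-enriched list fell too (adjusted p = 0.0184 with an estimated correlation, 0.0967 with set as a factor).

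The Vip hexagon of section 1 lay at a medial-lateral coordinate of 1348 and a dorsal-ventral coordinate of 755, with 779 Vip counts of 396801, and the other hexagons of its library set had at most 2. It also held 27 counts of A730046J19Rik, a transcript with a dorsal-ventral slope of 1.77 that was chosen after its values were seen, and the others of its set had 0. A hexagon of a middle section under the wrong label cannot be told apart from the given one: the 20 genes closest to Vip had a score that differed by -0.778 from what its Vip level predicts from sections 5 and 7, where residuals of 25 hexagons ran from -1.13 to 0.837 and 1 was as low. Carry-over of 1 other library also stays open: of 18 libraries with as high a share of Vip, 14 had genes, up to 223, that were lower in this hexagon than carry-over of Vip would bring, but 4 had 0. Of the 27 counts of A730046J19Rik, carry-over from any of the 18 would bring at most 6.67, and from those 4 at most 3.71. Vip expression in this hexagon, which the position given by the design allows, was not tested.

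Along the anterior-posterior coordinate, 28 genes were called in sections that library sets follow. With set as a factor in a fit over hexagons, 14 of the 28, or 50%, kept their sign, the median ratio of slopes was 0.0143 and standard errors grew by a median ratio of 6.74. Position and library set cannot be told apart for these genes, because little of the coordinate is left within a set. A biological difference between sections stays open as well.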

How the results depend on the processing

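The camera fits with library set or without the low-depth libraries, the pair correlations without those libraries, and the anterior-posterior fit with genes detected as a covariate were chosen after seeing the data, and the other alternatives before. Of 84 called slopes of named genes with 1636 alternative values, 1173 kept direction and side of the threshold, 453 kept direction and no longer passed, and 10 turned. The slopes of Vip, Ppp1r1a, Syt1 and Pou2f2 along the dorsal-ventral coordinate, and of Calcr and Peg10 along the medial-lateral coordinate, passed in every alternative run, and that of Slitrk5 along the anterior-posterior coordinate no longer passed in 16 of 21. The 10 that turned did so along the anterior-posterior coordinate in the fit over hexagons with library set as a factor, to slopes of -0.0745 for Plk2, -0.228 for Sh3gl2, -0.333 for Hadhb, 0.616 for Rtl1, 0.0168 for Cfap44, 0.445 for Zfp318, 1.52 for Plekhn1, 0.939 for Cacna2d2, 0.256 for Exd2 and 1.5 for Lars2. Against 91, 158 and 233 genes for the dorsal-ventral, medial-lateral and 5-term tests, DESeq2 gave 154, 352 and 394, and no filter 417, 631 and 2710. Limma on log2(RPKM + 1) gave 152 dorsal-ventral and 409 5-term genes. Library set as a factor gave 14 medial-lateral and 140 5-term genes, and a split at the section median 14 dorsal-ventral and 65 medial-lateral genes. Against 28 anterior-posterior genes, DESeq2 gave 446, no filter 51, a mean CPM of 10 or more 68, and limma on RPKM 2 with either pseudocount. Over hexagons, edgeR gave 337 genes, limma-voom with section as a random block 823, library sets C to H alone 410, genes detected as a covariate 394, and library set as a factor 0, with 408 at unadjusted p under 0.05. The edgeR fits over hexagons take hexagons of a section as separate. For these differences the cause was not tested. Leaving out 1 section at a time gave 47 to 138 dorsal-ventral genes (56, 47, 49 and 138 without section 4, 5, 6 and 8), 31 to 187 medial-lateral genes (85, 73 and 31 without section 3, 6 and 7), 85 to 279 5-term genes (123, 85 and 147 without section 5, 6 and 7) and 1 to 79 anterior-posterior genes (14, 16, 12, 1 and 79 without section 1, 4, 6, 7 and 8), with fewer hexagons or sections in each. Scaling by library size alone gave 58 higher and 51 lower dorsal-ventral genes against 58 and 33, 96 and 89 medial-lateral genes against 94 and 64, and 8 higher and 16 lower anterior-posterior genes against 13 and 15. The dorsal-ventral balance did not turn in any alternative run. The medial-lateral balance turned with no filter, to 247 higher and 384 lower, without section 7, to 9 and 22, and with the split at the median, to 31 and 34. The anterior-posterior balance turned, to more higher than lower genes, with library sets C to H alone (315 and 95), over hexagons in edgeR (182 and 155), with genes detected as a covariate (215 and 179), with no filter (26 and 25), without section 1 (10 and 4), 6 (7 and 5) and 7 (1 and 0), and in limma on RPKM (2 and 0). With an estimated correlation, camera called 1, 4 and 0 lists along the dorsal-ventral, medial-lateral and anterior-posterior coordinates against 4, 7 and 5, and along the last of these 2 lists had an unadjusted p under 0.05. There fry, which sets no list against other genes, called 4 lists. The count of pairs past the threshold stayed between 5 and 8. No paired analysis was possible because the hexagon numbers only name samples and the coordinates are continuous. Without the 5 low-depth libraries, which held from 11905 to 176618 counts, the dorsal-ventral, medial-lateral, 5-term and anterior-posterior counts were 88, 163, 209 and 26, and depth was not tested as a limit in another way. Differences in Grp and other sparse transcripts between single hexagons were not detectable where counts were at or near 0.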

Other observations

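The tests of respiratory chain and ATP synthase genes and of peaks along the sections were chosen only after the result was seen. Those of the 2 added gene pairs were chosen after the data were examined but before their own results were seen.

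Nuclear genes of the mitochondrial respiratory chain and ATP synthase rose with the medial-lateral coordinate as a group. Of 73 such genes, 71 had a positive slope, 16 passed over all genes tested, and the median slope was 0.12 (camera with an estimated correlation, p = 5.97e-05, and 0.000337 with library set as a factor). Along the dorsal-ventral coordinate their median slope was -0.04, 2 fell, and the p was 0.0191. Across genes, the medial-lateral slope statistic had a Spearman correlation of -0.143 with gene length, and this trend was not removed for the group. Hexagons may share an animal, so these p-values are too small.

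Calcr, the calcitonin receptor, and Avp rose and fell together across hexagons beyond section and the 5 position terms. Residuals from these gave r = 0.706 and rho = 0.699 (permutation p = 1e-05, the smallest these permutations can give, adjusted p = 2e-05 over 2 pairs). Sharper patterns of position, or patterns that differ between sections, can remain in these residuals. Without the 2 hexagons farthest from the median of Avp, r was 0.674, and r was positive in 8 of 8 library sets. A730046J19Rik went with Vip in the same way (r = 0.414, rho = 0.395, permutation p = 0.00043), with r = 0.416 without 2 hexagons and a positive r in 7 of 8 sets. It was at 0 CPM in most hexagons, among them all of set H, so the sign of r within single sets says little. The Vip-rich hexagon of section 1, whose label or carry-over stays open, held 69.1 CPM of it and enters this pair. Both pairs were chosen after the genes' slopes had been seen, and hexagons may share an animal.

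Some transcripts followed a curve along the anterior-posterior coordinate. A quadratic anterior-posterior term over the 8 sections passed in 303 genes by edgeR. It was negative, called a peak here, in 190 and positive, called a trough, in 113. The highest count in other orders of the sections was 124 among 100 orders. Whether the turn fell in the middle sections, or a slope was absent, was not tested. Where the summed hexagons lay within each section can enter this term, and Calcr and Peg10, named below, also fell with the medial-lateral coordinate. The Prok2 receptor Prokr2 (quadratic term -0.79, adjusted p = 8.78e-06), the vesicle protein Syt10 (-0.51, adjusted p = 0.00299) and Grp (-2.43, adjusted p = 0.0157) peaked, and Calcr (1.18, adjusted p = 0.00485), Peg10 (0.50, adjusted p = 0.00485) and the neuropeptide Gal (1.55, adjusted p = 0.00913) had a trough. Vip, highest in section 6 in the plot of peptides by section, did not pass (adjusted p = 0.716), so a peak shared by Vip and Grp stays open. The Vip-rich hexagon of section 1, whose label or carry-over stays open, enters this Vip test. Prokr2, Syt10, Calcr, Peg10 and Gal were chosen after their values were seen, and library sets follow the sections here too.

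The dorsal-ventral slope itself changed along the anterior-posterior coordinate in 2 genes, with 722 at unadjusted p under 0.05. These were the neuropeptide Trh (change of slope 1.97, edgeR adjusted p = 0.00527) and the inositol trisphosphate receptor Itpr1 (0.52, adjusted p = 0.0099), both chosen after their values were seen. For the medial-lateral slope edgeR called 0 genes, with 600 at unadjusted p under 0.05.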
